A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

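Genomic DNA of fission yeast was measured on 12 two-colour tiling arrays, 6 for cdc25-22 rif1Δ and 6 for cdc25-22 rif1Δ rad3Δ. The cdc25-22 mutation is a temperature-sensitive block before mitosis, used here to synchronise the cells. Per the labels' protocols, cells were held for 4 h at 36.5 °C and released at 25 °C, and 6 mM hydroxyurea, which slows forks by limiting nucleotides, was added 5 min later. Unreplicated DNA was taken at that moment. S phase DNA was taken once an undisturbed culture would have finished replication. Both channels of an array held DNA of the same strain, so each array compared copied with uncopied DNA. The label of 1 array (rif1Δ rad3Δ replicate 2, S phase DNA in Alexa 555) described the sampling differently, as times 90 and 0 with no unit, and gave no time for the drug. It was kept in its group.

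The deposited spot intensities came from Agilent Feature Extraction 10.7.3.1, per the file headers, after background subtraction, spatial detrending and a linear dye normalization with 1 factor per channel. The deposited log10 ratio of red over green, written by the same software per the file headers, served only to check the direction of each ratio. Extraction used a ChIP protocol for rif1Δ replicate 2 and a CGH protocol for the other 5 replicates, per the file headers. Green was Alexa 555 or Cy3 and red was Alexa 647 or Cy5, per the labels. The labels gave the dye of each DNA, and ratios were turned so that a positive value means more S phase DNA. In rif1Δ rad3Δ replicate 3 the numbering of the dye-swap arrays ran opposite to the other replicates, which the dye labels settled.

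Each array carried 45220 spots, of which 42707 were genomic probes and 2513 were controls. The genomic probes had a median length of 60 bases and a median spacing of 265 bp, and 18958 lay on chromosome I, 15339 on chromosome II, 8344 on chromosome III and 66 on mitochondrial DNA. Between 97.2% and 99.9% of probes were well above background in the green channel, and between 90.9% and 100% in the red. The median processed signal per array was 1052 to 1364 in green and 1062 to 1400 in red. The scanner software marked 0.939% to 40.7% of probes as outliers.

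Control spots and outlier-marked spots were left out. A probe entered a replicate only if it was unmarked on both of its dye-swap arrays, a rule chosen after the share of marked spots had been seen. Log2 of S phase over unreplicated processed signal was centred on each array's median over nuclear probes, with no loess or quantile step. The dye-swap arrays of a replicate held the same pair of extracts, so they were averaged and counted as 1 replicate, giving n = 3 per strain. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Replicates used 90.0%, 97.2% and 78.2% of probes in rif1Δ and 40.6%, 88.9% and 90.1% in rif1Δ rad3Δ. The number of arrays and these shares limit the precision.

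Probes were averaged in 1-kb windows that held at least 2 probes. Of 12129 windows with a probe, 11458 (94.5%) had at least 2 replicates per strain and were tested, and 4706 were complete in all 6 replicates. Limma 3.58.1 in R 4.3.3 (lmFit and eBayes) tested each strain mean against 0 and the difference between strains, with Benjamini-Hochberg adjustment at 0.05. A window above 0 held more S phase over unreplicated DNA than the median window of the genome, read here as copying in more cells. The ratio also rose with AT content away from peaks in some replicates, so a positive value alone does not prove copying. The centring fixes how many windows fall below 0. Origin peaks were local maxima of the strain mean smoothed over 3 windows, at least 0.2 high, 0.1 prominent and 5 windows apart, with a summit window past the limma test. Peaks of the mean of both strains, called the same way, are named common peaks. A peak value is the mean of its summit window and 1 window on each side. Region classes and gene lists were compared between strains by a two-sided exact permutation test of replicate means and by limma's fry, which asks whether the windows or genes of a set move one way on balance. With 3 replicates against 3 the exact test cannot go below p = 0.1. Gene values were the means of probes inside a gene or within 500 bp. Positions of classes and peaks were compared with 10000 rotations of the same set along the chromosomes.

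Positions are those of the array design, whose header names the build Spombe:NCBI:Feb2002. Genes came from the reference assembly ASM294v3. The GC content of the reference followed probe brightness at the design's own positions in 44 segments of 250 kb (r = 0.44 to 0.64 across probes). It failed to do so in the 8 segments right of centromere 1 (r = -0.07 to 0.03), where a shift of 6140 bp gave the highest match (r = 0.52 to 0.71). Nothing was shifted; no gene is named in those segments, and 85.8% of nuclear probes lay where genes could be named. The annotation used here has no mat2 entry, so the mating-type class rests on the mat1 and mat3 entries. Centromeres 2 and 3 were the longest gap between neighbouring protein-coding genes of the chromosome. Centromere 1 began at that gap's start, and its end was read from the array probes, because the reference does not match the design beyond it.

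The text names the fixed loci rif1, rad3, ura4, hus5, mat2, mat3, the 3 centromeres and the chromosome ends. It names the 8 highest peaks of each strain, the common peaks with the largest differences among those past the threshold, and 2 to 4 members of each of 8 gene lists with the largest absolute difference between strains. These rules, the classes, the lists and the tests were fixed before the data were examined. No common peak passed the threshold, so that part of the rule named none. The list of ribosomal protein genes was drawn by name and also holds RNase P subunits, whose names begin in the same way.

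The window test was tested on simulated data with the observed spread over 11458 windows. For the difference between strains it recovered 0% of 200 windows changed by 0.1 (log2), 19.0% at 0.2, 91.5% at 0.3 and 99.5% at 0.4. With no change it made 5 calls higher and 1 lower. Against the median in rif1Δ it recovered 91.0% of windows raised by 0.2. All of 150 simulated peaks were recovered, with 151 called and 0 false. These peaks were made 0.4 high with noise independent between windows, so they do not test calls near the height minimum of 0.2.

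The alternatives changed the background correction (normexp with an offset of 50, run on median signals), loess within arrays, the centring, the amplitude, the filter on dim or saturated probes, the dye orientation, the window size and summary, the peak minimums, the overlap distance, the replicate number and the slide as blocks, limma's trend and robust settings, single-strain fits, the telomere class, the gene flank and the replicates in use. Added after seeing the data were outlier-marked spots kept (the first exploration used this setting), complete windows alone, replicate 1 of both strains left out, and a base composition trend removed. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, Biopython 1.88, matplotlib 3.10.9 and statmod 1.5.0. The 6 slides held 1 replicate each, so slide entered as a random block over single arrays. The tests were unpaired.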

Results

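Replication origins were mapped in synchronised fission yeast (Schizosaccharomyces pombe) that lacked rif1 alone or both rif1 and rad3. Rif1 is a chromatin protein known to delay late origins and to act at telomeres, and Rad3 is the ATR-family checkpoint kinase that holds back late origins when forks stall. Cells entered S phase in hydroxyurea, which keeps forks near the origins that fired, so DNA close to an origin that fired is enriched over unreplicated DNA of the same strain. The data comprised 3 replicates per strain, each a dye-swap pair of arrays, and the design implies 3 questions: where DNA was copied in rif1Δ, where it was copied in rif1Δ rad3Δ, and where the strains differed. Arrays of a strain with rif1 were not analysed here, so nothing below measures the loss of rif1 itself.

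The deleted genes were read first. In rif1Δ, the 16 probes inside rif1 (chromosome I, 2766273 to 2770704) lay at -4.04 ± 1.54 (log2 relative to the array median, SD, n = 3). In rif1Δ rad3Δ they lay at -5.98 ± 0.37. The 33 probes inside rad3 (chromosome II, 904184 to 913629) lay at -0.37 ± 0.16 in rif1Δ and at -4.48 ± 1.13 in rif1Δ rad3Δ, so both genes were dim where the labels say they are deleted. Of the 33 rad3 probes, the 24 between 904607 and 911114 lost signal in the double mutant, and the 8 past 911114 kept it. The remaining probe, at 904323, fell from -1.48 to -2.91. In rif1Δ replicate 3 and rif1Δ rad3Δ replicate 3 the deleted gene kept a low signal above background.

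The profiles of the replicates resembled one another more closely in rif1Δ rad3Δ than in rif1Δ. Across windows, which are not independent replicates, Pearson's r between replicates was 0.86 to 0.89 within rif1Δ rad3Δ and 0.69 to 0.79 within rif1Δ. Between strains it was 0.68 to 0.86, and the strain means correlated at 0.89. The dye-swap arrays of one replicate correlated at 0.30, 0.58 and 0.69 in rif1Δ and at 0.72, 0.88 and 0.82 in rif1Δ rad3Δ. By this measure the rif1Δ profile rests on less reproducible arrays, replicate 1 above all. The spread of differences between neighbouring log ratios per array overlapped, at 0.15 to 0.23 in rif1Δ and 0.097 to 0.24 in rif1Δ rad3Δ. Its highest value came from an array of rif1Δ rad3Δ replicate 1.

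**Figure D1:**
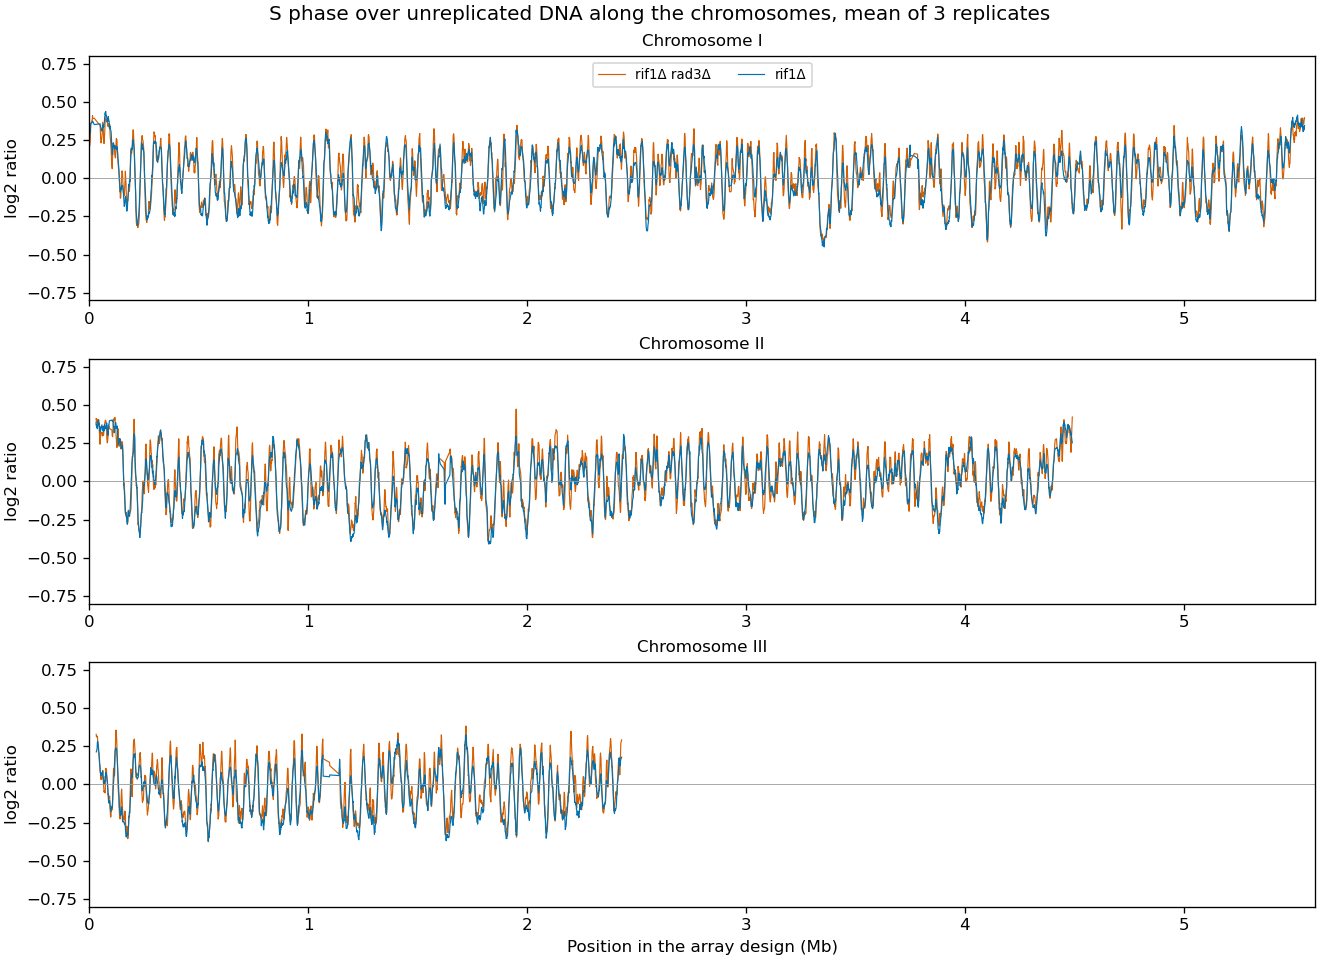
Mean log2 ratio of S phase over unreplicated DNA in 1-kb windows (y axis) along the 3 chromosomes (x axis, Mb in the array design), with 1 line per strain averaged over 3 replicates. Each line is drawn as a rolling mean over neighbouring windows. Both lines rise at the ends of chromosomes I and II, where the means were 0.34 in rif1Δ and 0.33 in rif1Δ rad3Δ. Before that smoothing, the strain means correlated at r = 0.89 over all tested windows, the ends included.

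In rif1Δ, the ratio was highest at the ends of chromosomes I and II. The 235 windows within 100 kb of those ends had a mean log2 ratio of 0.34 ± 0.054 (SD, n = 3), against -0.0122 ± 0.0030 on the chromosome arms, and 99.2% of them were above the genome median. Within 200 kb the mean fell to 0.177. The mating-type region of chromosome II, taken with 10 kb on each side and only partly heterochromatic, stood at 0.17 ± 0.03 with 82.1% of its 28 windows above the median. The DNA within 50 kb of the ends of chromosome III, beside the ribosomal DNA, stood at 0.096 ± 0.013. The 50 kb on each side of the centromeres was low, at -0.071 ± 0.0013, with 15.3% of windows above the median. Over the genome, limma placed 3413 of 11458 windows (29.8%) above the median and 3588 below it (adjusted p under 0.05). That count depends on the centring, since it was 743 when the most common value of each replicate was set to 0.

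The rif1Δ profile held 139 origin peaks with a median spacing of 73.0 kb. The number was 34 with centring on the mode and 86 without rif1Δ rad3Δ replicate 3, which leaves fewer windows to test. Of the 8 highest, 7 lay near an end of chromosome I or II. The highest, in window 73001 to 74000 of chromosome I between SPAC977.17 and SPAPJ695.02, reached 0.48 ± 0.13 (limma adjusted p = 0.000361 at its summit). Windows starting at 5519001 and 5497001 of chromosome I, where no gene is named, reached 0.43 ± 0.075 and 0.41 ± 0.094, and the peak at 5497001 lost its call with S phase DNA in Alexa 647 alone (0.28). On chromosome II the peak between fub2 and nrg1 (start 4455001) reached 0.43 ± 0.080, that in SPBC359.01 (106001) 0.41 ± 0.03, that between SPBPB21E7.09 and SPBPB10D8.01 (80001) 0.41 ± 0.05, and that between SPBPB2B2.06C and SPBPB2B2.07C (4472001) 0.37 ± 0.083. The remaining one lay on the arm of chromosome II between the tRNA genes SPBTRNAGLY.05 and SPBTRNAARG.04 (326001) and reached 0.35 ± 0.04. Among the fixed loci, hus5, which encodes a SUMO-conjugating enzyme and lies beside the origin ars1, stood at 0.26 ± 0.04. The nucleotide synthesis gene ura4, beside ars3002, ars3003 and ars3004, stood at 0.19 ± 0.13, and mat3 at 0.22 ± 0.15. The ends of chromosomes I and II stood between 0.30 and 0.37, the left end of chromosome III at 0.21 ± 0.0054 and its right end at 0.027 ± 0.018. Centromeres 1, 2 and 3 stood at 0.15 ± 0.054, 0.020 ± 0.073 and 0.091 ± 0.026.

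In rif1Δ rad3Δ the same parts of the genome led. The windows within 100 kb of the ends of chromosomes I and II had a mean of 0.33 ± 0.071, with 94.0% above the median, and the arms stood at 0.0040 ± 0.014. Within 200 kb of those ends the mean was 0.184, above the 0.177 of rif1Δ, so the order of the strains turned. The mating-type region stood at 0.21 ± 0.057, the rDNA-proximal DNA at 0.13 ± 0.03 and the pericentromeric DNA at -0.053 ± 0.016. Limma placed 3485 windows (30.4%) above the median and 3424 below it (1985 above with normexp, and 1527 above of fewer tested windows without rif1Δ rad3Δ replicate 3), and 2704 windows were above it in both strains. Only 13 windows were above in one strain and below in the other.

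The rif1Δ rad3Δ profile held 306 origin peaks with a median spacing of 36.0 kb. The number was 322 with centring on the mode and 201 without rif1Δ rad3Δ replicate 3. The highest peak lay on chromosome I between SPAC212.07C and SPAC212.12 (start 15001) and reached 0.51 ± 0.21 (limma adjusted p = 0.000206 at its summit). The peak on chromosome II between the flocculin gene pfl3 and the clathrin adaptor gene apl2 (674001) reached 0.51 ± 0.33, with replicate 1 at 0.89 and the others at 0.26 and 0.38. Near the left end of chromosome II the peak between SPBPB21E7.08 and SPBPB21E7.09 (74001) reached 0.45 ± 0.089, and that between alr2, an alanine racemase gene, and aat1 (110001) reached 0.44 ± 0.12. On chromosome III the peaks between the glutathione transferase gene gst1 and SPCC191.10 (1721001) and in SPCC622.07 (1409001) reached 0.44 ± 0.15 and 0.43 ± 0.13. On the arm of chromosome II the peaks in lcl3 (3235001) and in duo1, which encodes a kinetochore DASH subunit (2798001), both reached 0.43, with SDs of 0.19 and 0.16. Of these 8 peaks, 4 lost their call under 1 alternative each: those at 15001 (0.39) and 1409001 (0.30) with normexp, and those at 674001 (0.37) and 2798001 (0.33) with S phase DNA in Alexa 647 alone. The locus hus5 stood at 0.24 ± 0.02, with a peak 1.03 kb away, ura4 at 0.08 ± 0.05 and mat3 at 0.42 ± 0.12 with a peak beside it. The ends of chromosomes I and II stood between 0.36 and 0.42, and those of chromosome III at 0.22 ± 0.03 and 0.068 ± 0.039. Centromeres 1, 2 and 3 stood at 0.13 ± 0.11, 0.057 ± 0.12 and 0.17 ± 0.10.

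Between the strains, 117 of the 139 rif1Δ peaks (84.2%) had a rif1Δ rad3Δ peak within 3 kb, against a mean of 24 and at most 79 in 1000 rotations. Those 117 made up 38.2% of the rif1Δ rad3Δ peaks. Of the other 189 peaks of the double mutant, 139 had a summit window that was also above the median in rif1Δ. Most of these places were thus above the median in both strains, a call that depends on the centring. Counted in each replicate without the limma condition, a test added after the results were seen, peaks numbered 216, 152 and 197 in rif1Δ and 244, 259 and 336 in the double mutant (exact permutation p = 0.1, the smallest possible). In complete windows they numbered 106, 93 and 129 against 227, 133 and 215 (exact permutation p = 0.1). A height minimum of 0.4 left 5 rif1Δ and 9 rif1Δ rad3Δ peaks. With 1 dye orientation alone the numbers came closer, 197 and 245 peaks with S phase DNA in Alexa 647 and 264 and 333 in Alexa 555.

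At the 211 common peaks the mean log2 ratio was 0.22 ± 0.02 in rif1Δ and 0.31 ± 0.059 in rif1Δ rad3Δ (SD, n = 3; two-sided exact permutation p = 0.2). The median difference was 0.092, and 188 common peaks (89.1%) had the higher mean in the double mutant. That median was 0.033 with S phase DNA in Alexa 647 alone and 0.040 in Alexa 555 alone. Without replicate 1 of both strains it was 0.059, and with centring on the mode 0.20. Limma called 0 common peaks higher and 0 lower (smallest adjusted p = 0.105), and at an unadjusted p under 0.05 it had 66 higher and 0 lower. That unadjusted count was not stable. It was 5 higher with normexp, and 13 higher among the 126 common peaks of windows with reference sequence and the AT trend removed. It was 14 higher and 3 lower with S phase DNA in Alexa 647 alone, and 16 higher and 2 lower in Alexa 555 alone. Without replicate 1 of both strains it was 0 higher and 2 lower. It rose to 111 higher with centring on the 25th percentile and to 116 higher among peaks called at a height minimum of 0.1. Of the 195 common peaks measured in all 6 replicates, the double mutant lay wholly above rif1Δ at 53 and wholly below at 1. Together these were 27.7% where chance gives 10% on average. Peaks share shifts of whole replicates, so such a share can lie far from that average by chance. Fry over the 98 common peaks whose summit window was measured in all 6 replicates gave a p of 0.0511. In the main fit, then, no single peak passed. Averaged over common peaks, rif1Δ rad3Δ replicate 2 (0.245) lay below rif1Δ replicate 3 (0.252), so a difference in height is not established. Limma's trend and robust settings called 29 common peaks higher, and keeping outlier-marked spots called 28.

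**Figure D2:**
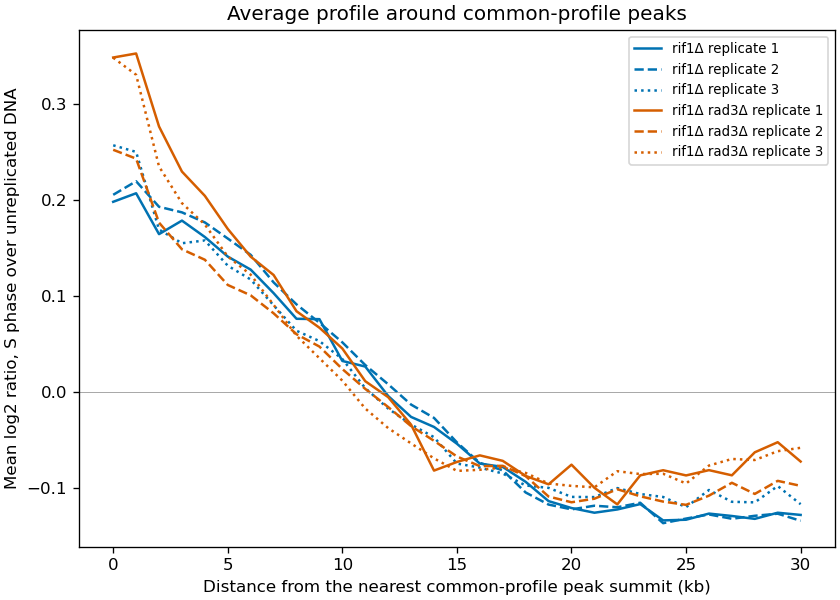
Mean log2 ratio of S phase over unreplicated DNA (y axis) against the distance from the nearest common-peak summit (x axis, kb), with 1 line per replicate. At the summit rif1Δ replicates lay at 0.20, 0.21 and 0.26 and rif1Δ rad3Δ replicates at 0.35, 0.25 and 0.35, so rif1Δ rad3Δ replicate 2 overlapped rif1Δ, and all lines fell below 0 before 15 kb.

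The rise from the valleys to the peaks gave the same order. The mean at common peaks minus the mean 15 to 20 kb away was 0.31 ± 0.03 in rif1Δ and 0.40 ± 0.053 in rif1Δ rad3Δ (exact permutation p = 0.2). The spread of whole profiles, as the SD over windows, was 0.18 ± 0.0020 in rif1Δ and 0.19 ± 0.02 in rif1Δ rad3Δ, a difference of 0.0080 (exact permutation p = 0.7). Window by window, limma called 0 windows higher and 0 lower in the double mutant (smallest adjusted p = 0.0964). At an unadjusted p under 0.05 it had 858 higher and 349 lower, where chance alone gives 573 in all on average. With each replicate centred on its most common value these became 1707 higher and 4 lower, and 69 windows passed as higher. That centring moved the medians by -0.11 to 0.11. Among the 4706 complete windows the replicates did not overlap at 546 above and 297 below, together 17.9% where chance gives 10% on average. Windows share shifts of whole replicates, so counts of windows can lie far from such averages by chance. The median absolute difference per window was 0.053 and the median half-width of its 95% interval was 0.13.

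No region class passed a test between strains, which with 3 replicates each does not show that none differed. The ends of chromosomes I and II differed by -0.0126 (exact permutation p = 0.9). Against 10000 rotations of the windows this difference lay at percentile 0 and that of the centromeres at 99.98, but rotations ask about position and leave out the spread between replicates. The 20 centromeric windows stood at 0.0425 ± 0.036 in rif1Δ and 0.10 ± 0.088 in the double mutant (exact permutation p = 0.4). The pericentromeric DNA differed by 0.018 and chromosome III by 0.026, both with replicates of the strains apart (exact permutation p = 0.1, the smallest possible). The chromosome arms differed by 0.016 and chromosomes I and II by 0.014 and 0.015. The pericentromeric difference was therefore close to that of the genome at large, and it lay at percentile 34.9 of the rotations. For chromosome III fry gave a p of 0.0134, or 0.134 adjusted over 10 classes, and for the pericentromeric DNA an adjusted p of 0.24. With arrays of S phase DNA in Alexa 555 alone, the differences of centromeric, pericentromeric, mating-type and rDNA-proximal DNA became negative.

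**Figure D3:**
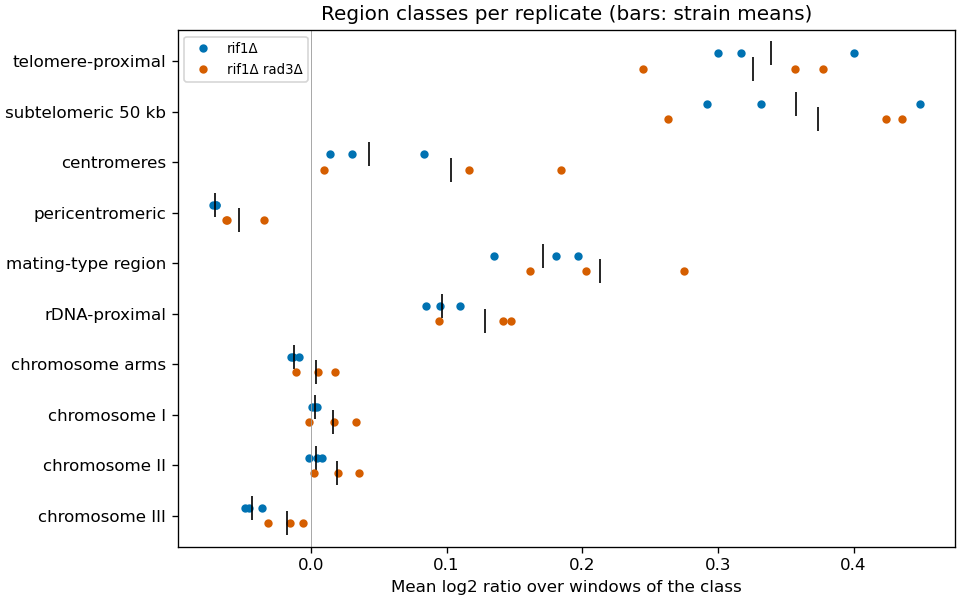
Mean log2 ratio over the windows of each region class (x axis) for each class (y axis), with 1 point per replicate coloured by strain and a bar at each strain mean. The telomere-proximal points spread from 0.24 to 0.40 and overlap between strains, and the points of chromosome III lie below 0 in all 6 replicates.

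Gene lists mark places in the genome, and transcripts were not measured. Of 4521 genes, 1628 were above the median in rif1Δ and 1761 in rif1Δ rad3Δ, with 0 higher and 0 lower between strains by limma (smallest adjusted p = 0.167; 535 higher and 179 lower at an unadjusted p under 0.05). Among 111 measured tRNA genes, 55 were above the median in rif1Δ and 75 in the double mutant, and the list mean was 0.076 ± 0.033 and 0.14 ± 0.05 (exact permutation p = 0.1; fry adjusted p = 0.205). Adjusted over the list alone, 19 tRNA genes were higher and 0 lower, and 37 were higher at an unadjusted p under 0.05. The widest differences were at SPBTRNATHR.07 (0.37, SE 0.092), SPATRNAPRO.01 (0.35, SE 0.091) and SPCTRNASER.07 (0.32, SE 0.046). Of 30 measured 5S rRNA genes, 11 were above the median in rif1Δ and 19 in the double mutant, and 1 was higher adjusted over the list alone. Their means were 0.056 ± 0.032 and 0.15 ± 0.05 (exact permutation p = 0.1; fry adjusted p = 0.205). SPRRNA.39, SPRRNA.07 and SPRRNA.30 differed by 0.27, 0.24 and 0.23. The 19 tRNA calls fell to 0 with either dye orientation alone, with normexp and without dim or saturated probes. They lay between 1 and 7 without rif1Δ replicate 1 or 2 or rif1Δ rad3Δ replicate 1 or 3. They numbered 3 with loess, with centring on the 25th percentile and without replicate 1 of both strains, and 43 with centring on the mode. Without the 500 bp flank they numbered 0, but the named tRNA genes are shorter than the median probe spacing of 265 bp. Few such genes can then hold the 2 probes required, so that 0 says nothing about the calls. The tRNA mean difference of 0.069 became 0.010 with normexp, 0.022 with Alexa 555 alone, 0.11 with Alexa 647 alone and 0.19 with centring on the mode. The 5S rRNA difference of 0.089 became 0.032 with normexp, 0.032 with Alexa 555 alone and 0.21 with centring on the mode.

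The other lists gave smaller differences, with 0 members higher or lower over the list alone by limma. Of 6 core histone genes, the neighbours hta1 and htb1, which encode H2A and H2B, were above the median in both strains, at 0.25 ± 0.05 and 0.26 ± 0.05 in rif1Δ and 0.33 ± 0.12 and 0.27 ± 0.079 in the double mutant. The H4 gene hhf2 lay low in both, at -0.34 ± 0.02 and -0.26 ± 0.03. Ribosomal protein genes were above the median for 46 of 125 in rif1Δ and 50 in the double mutant, with the widest differences at rps502 (0.16), rpl3703 (0.15) and rpl402 (0.14). Of 14 measured wtf genes, a family of spore killers, 5 and 6 were above, and wtf20, wtf25 and wtf22 differed by 0.19, 0.16 and 0.11. Of 59 measured snRNA and snoRNA genes, 24 and 25 were above, and snu6, snoR68 and snR5 differed by 0.17, 0.16 and 0.13. The telomere-end helicase gene tlh1, the 1 measured of 2, stood at 0.29 ± 0.063 and 0.29 ± 0.11. None of the 9 annotated Tf2 genes was measured. At an unadjusted p under 0.05 these lists held 1 histone gene, 10 ribosomal protein genes, 3 wtf genes and 5 snRNA or snoRNA genes higher, and 4 ribosomal protein genes and 2 snRNA or snoRNA genes lower. Fry adjusted p-values were 0.205 for histone genes and 0.268 for the ribosomal protein, wtf and small RNA lists.

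Peak summits lay between genes more often than rotated peaks did. In rif1Δ, 54.7% of 117 summits with annotation were intergenic, against a mean of 20.9% in 10000 rotations, and in rif1Δ rad3Δ 57.9% of 259 summits, against 21.1%. The AT content of summit windows was 66.6% and 68.4%, against 63.9% in rotations of either set. All 4 comparisons gave a permutation p = 2e-04, the smallest that 10000 rotations can give, and the same after adjustment. The ratios themselves rose with AT content more than 10 kb from common peaks in rif1Δ replicate 3 and in all replicates of the double mutant. With that trend removed, 32.7% of rif1Δ summits were intergenic. With S phase DNA in Alexa 647 alone the share in rif1Δ was 27.3%, and with normexp the share in rif1Δ rad3Δ was 37.5%. Rotations were run for the main sets alone, and gave 13.7% to 28.2% for the 117 summits and 16.2% to 26.2% for the 259. These settings called other sets of peaks, so whether their shares exceed those of rotated peaks was not tested. The size of the excess therefore depends on the processing.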

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

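All tests in this part were chosen after the results they concern had been seen, except the limma test of SPCTRNASER.07. Groups of 3 replicates were not searched for outlying samples.

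Sequence of deleted genes was detected in the third replicate of each strain. The 14 deleted rif1 probes lay 1.59 to 2.99 (log2) above the 507 negative control spots in the 4 channels of rif1Δ replicate 3, and the 24 deleted rad3 probes lay 2.23 to 2.98 above them in rif1Δ rad3Δ replicate 3. In the other replicates that lack the gene these medians were -0.24 to 1.28. The remaining rif1 signal came to 10.6% of the array median, and the remaining rad3 signal to 5.58% of that in rif1Δ.

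A high floor of the rif1Δ rad3Δ replicate 3 slide is argued against, because the rif1 probes on the same arrays lay at -0.028 to 0.18 while the lowest rad3 value was 2.23. The brightness of the deleted rad3 probes in that replicate followed that of the same probes in rif1Δ, with r = 0.80 in green and 0.81 in red across 24 probes, against 0.23 and 0.22 in replicates 1 and 2. DNA that carries rad3, in the extract or left on the slide, is therefore a candidate explanation there, and the data cannot separate those routes. Since the rif1 probes lay at -0.028 to 0.18, such DNA would carry rad3 without a like amount of rif1, as the rif1Δ strain does. Which strain it came from was not tested. Neither test could be made for rif1Δ replicate 3, which has no second deleted gene and no strain with rif1 beside it, so its source stays open. No biological explanation was tested.

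The tRNA gene SPCTRNASER.07 (chromosome III, 473199 to 473280) lay below the median in each measured rif1Δ replicate and above it in each rif1Δ rad3Δ replicate, a difference of 0.32 (SE 0.046). Only 2 rif1Δ replicates measured it, and limma over all genes gave adjusted p = 0.167.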

How the results depend on the processing

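Of 1044 comparisons of a result with 34 alternative settings, 887 were counted as unchanged, 122 values moved, and 12 lost and 23 gained a call. Unchanged meant a count or percent within 1.5 times, a value within the replicate spread, or a test on the same side of the threshold. Differences of region classes had only the exact test here, which cannot go below p = 0.1. They therefore counted as unchanged whatever their sign. No called value changed sign, while 34 values without a call had the opposite sign. Alternatives chosen after seeing the data were outlier-marked spots kept, complete windows alone, replicate 1 of both strains left out and the AT trend removed. The median difference at common peaks stayed above 0 in each alternative that gave it, from 0.014 at a height minimum of 0.4 to 0.20 with centring on the mode. The cause was not tested for any change below, except where fewer or more windows or probes were tested.

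Windows above the median in rif1Δ and rif1Δ rad3Δ numbered 1997 and 1985 with normexp, 6734 and 6257 with centring on the 25th percentile, 2107 and 2192 in 2-kb windows, 6746 and 7101 as single probes, and 1473 and 1652 in complete windows. Centring on the mode gave 743 such windows in rif1Δ, and 69 windows higher between strains. Peaks in rif1Δ and rif1Δ rad3Δ numbered 34 and 322 with centring on the mode, 143 and 227 with normexp, and 261 and 390 with the 25th percentile. They numbered 264 and 333 with S phase DNA in Alexa 555 alone, 230 and 353 at a height minimum of 0.1, and 5 and 9 at 0.4. In complete windows they numbered 84 and 195. In windows with reference sequence they numbered 117 and 259 before the AT trend was removed, and 107 and 198 after. With S phase DNA in Alexa 647 alone the amplitude difference was -0.015 (exact permutation p = 0.4).

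Common peaks higher in the double mutant numbered 1 with the 25th percentile, 1 without dim or saturated probes, 29 with trend and robust settings and 28 with outlier-marked spots kept. Windows lower in the double mutant numbered 1 without dim or saturated probes, 1 with trend and robust settings and 1 with the AT trend removed in windows with reference sequence. Without replicate 1 of both strains 1 window was higher, 4 were lower and 2 common peaks were lower. Without dim or saturated probes no centromeric window remained, so that class has no value there.

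Leaving out 1 replicate at a time gave 1515 to 3381 windows above the median in rif1Δ and 1527 to 3682 in rif1Δ rad3Δ, 0 to 1 higher and 0 to 4 lower between strains, 86 to 148 and 201 to 302 peaks, 0 to 1 common peaks higher and 0 to 2 lower, and 0 to 2 region classes past fry. The lowest counts of windows and peaks came without rif1Δ rad3Δ replicate 3, and the 4 lower windows and 2 lower common peaks without rif1Δ replicate 1. The 2 region classes passed without rif1Δ rad3Δ replicate 2. The 66 common peaks at an unadjusted p under 0.05 became 10 without rif1Δ replicate 1.

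The labels do not say that equal replicate numbers share a culture or day. Deviations of equal numbers correlated at 0.039, 0.17 and 0.33, and those of unequal numbers at -0.27 to 0.11. Shared handling of equal numbers therefore cannot be excluded, and the main tests leave it out. With the replicate block limma called 0 windows higher and 2 lower, and no other call changed; windows higher at unadjusted p under 0.05 numbered 927 and windows lower at unadjusted p under 0.05 numbered 408. With slide as a random block (consensus correlation 0.15 for windows) it called 0 higher and 0 lower, with 795 and 565 at an unadjusted p under 0.05. Marked spots limit the measurement most in rif1Δ rad3Δ replicate 1, which used 40.6% of probes. Normexp used median signals, since the files hold no mean signals.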

Other observations

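The tests of base composition, array quality, dye orientation, stress genes and unadjusted peaks in this part were chosen after the results had been seen. The splits of replicates for called windows, peaks and genes were planned.

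Mitochondrial DNA gave no ratio that the replicates of a strain shared. Its 66 probes stood at -0.34, -0.090 and 0.094 (log2 relative to the nuclear median) in rif1Δ replicates 1, 2 and 3. In rif1Δ rad3Δ they stood at 0.34, -0.20 and 0.033.

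Origin peaks were more numerous and, on average, higher in rif1Δ rad3Δ, with a median difference of 0.092 at common peaks. Noise in rif1Δ replicate 1 alone is argued against, because without it rif1Δ had 145 peaks and rif1Δ rad3Δ 287, but over windows the dye orientations correlated at most at 0.69 in rif1Δ and at least at 0.72 in rif1Δ rad3Δ, so this measure of array quality, unlike the share of marked spots, followed strain; peak means rose with it within rif1Δ and not within rif1Δ rad3Δ, and it cannot be told apart from strain. More than 10 kb from common peaks the ratio rose with AT content by 0.041, 0.0017 and 0.19 (log2 per 10 points) in rif1Δ. In rif1Δ rad3Δ it rose by 0.14, 0.14 and 0.19, so rif1Δ replicate 3 carried that trend too and it may account for part of the difference. In such windows with a genic centre the slopes were 0.016, -0.036 and 0.18 in rif1Δ and 0.086, 0.097 and 0.15 in rif1Δ rad3Δ. Windows far from common peaks can still hold peaks called in 1 strain alone, so removing the trend may also remove peak height. In windows with reference sequence, removing the trend took the median difference from 0.093 at 176 common peaks to 0.060 at the same peaks and 0.049 at the 126 called afresh, and the mean from 0.091 (SE 0.037) to 0.058 (SE 0.031) and 0.046 (SE 0.034), so as the whole source of the height difference the trend cannot be told apart from an effect of strain; peaks numbered 117 and 259 before and 107 and 198 after, so rif1Δ rad3Δ still had more. The loss of rad3, the biological explanation in the design, stays open, and nothing here separates it from these sources.

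The other splits of the 6 replicates are too few for a share under 0.05. The real split had 0 called windows, common peaks and genes by limma and the highest other split 1, so that 10 of 10 splits reach the real count by necessity and say nothing about chance. For common peaks at an unadjusted p under 0.05 the real split had 66 and the highest other 71, so 2 of 10 splits reached that count. The split with 71 set rif1Δ replicates 1 and 2 and rif1Δ rad3Δ replicate 2 against the rest.

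At 4 places on chromosome II the ratio differed between replicates of the same strain far more than elsewhere, over 6, 5, 3 and 2 windows. At lsd90 (1947985 to 1950255) it was -1.46 in rif1Δ replicate 1, 1.99 in replicate 2 and 1.07 in rif1Δ rad3Δ replicate 2, and rif1Δ replicate 2 also stood high at wwm2, hob1 and fib1 (1.74, 0.78 and 0.71). The fib1 place holds a peak counted among the 139 of rif1Δ and as shared between strains (2984001, between fib1 and nap2). Its values in rif1Δ replicates 1, 2 and 3 were 0.010, 0.78 and 0.097, so its height rests on replicate 2. A dye or single-array artefact is argued against, because in 100% of the 12 cases beyond 0.5 both dye orientations had the same sign. Heat and stress genes as a class are argued against too, since the 35 measured of 44 listed had a median percentile of replicate spread of 56.9, and 1 passed the 95th percentile. Material from these genes carried in single extracts could give such values, which was not tested.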
